A study of Mus musculus with 4 samples.

How the data were processed

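Gene expression was measured in spinal cord of adult female SJL/J mice, a strain susceptible to autoimmune demyelination, with and without AT-EAE. AT-EAE is adoptive-transfer experimental autoimmune encephalomyelitis, a mouse model of multiple sclerosis in which myelin-reactive T cells are transferred into recipients. Each extract was a pool of cords from 2 mice, and each 2-colour cDNA array carried 2 extracts of the same group, 1 in each channel. There were 4 arrays, 2 for control cord and 2 for AT-EAE cord, so that 4 extracts stood for each group. Array 1 of a group carried extracts 1 and 2, and array 2 carried extracts 3 and 4.

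The deposited value of each spot was taken to be a log2 ratio of the normalized signals of the 2 channels. The values were signed and had a median within 0.1 of 0 on every array, which a signal level would not have. Neither the base of the logarithm nor the channel in the numerator is given in the sources used here, so base 2 was assumed. A sign therefore has meaning only relative to other genes on that array, and folds hold only if the base was 2. Background correction, the filter on spots, the normalization method and the software of the authors are not given in the sources used here, and signal over background was not analysed here.

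Because both channels of an array held extracts of 1 group, these ratios carry no difference in level between AT-EAE and control cord. The planned test of that difference, limma on levels per array, was therefore not run. What the ratios measure is the difference between 2 extracts of 1 group, together with dye and technical noise.

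The arrays had 28704 spots each. Of these, 18511 were assigned to 1 gene, 937 to several genes and 9256 to none. Clone annotation came from the table of the array platform, and symbols were updated through their gene identifiers to the GRCm38.p6 gene table for 18267 spots and kept for 244. The assigned spots covered 10225 genes, and spots with no gene or several genes were never named. A gene's ratio was the mean over its spots with a value on that array. In all, 9006 genes had a value on at least 1 array, 5429 genes had one on all 4, and 10133 spots had one on all 4. The number of arrays, 2 per group, limits the precision. Every sample used was 1 of the 4 arrays, and columns of no sample used numbered 0.

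The spread on each array was the standard deviation estimated from the median absolute deviation (MAD) over genes, and the groups were compared by a 2-sided exact permutation test over the 6 splits of the 4 arrays. Genes with an absolute log2 ratio of at least 1, a 2-fold difference, were counted per array. A total of 24 gene lists was tested per array: MHC class II presentation, MHC class I and immunoproteasome, interferon response, T cell, B and plasma cell, microglia and macrophage, neutrophil, cytokines and chemokines, complement and acute phase, adhesion and vessel, astrocyte, oligodendrocyte and myelin, connexins and pannexins, neuron, cholesterol synthesis, cell cycle, immediate early and stress, oxidative phosphorylation, ribosomal protein, red blood cell, Schwann cell and nerve root, meninges and fibroblast, skeletal muscle, and ependymal and cilia. The oxidative phosphorylation and ribosomal protein lists were taken by symbol prefix, which also admitted assembly factors to the former and S6 kinase genes (Rps6ka5, Rps6ka6 and Rps6kc1) to the latter. The median ratio of a list with at least 3 measured genes was ranked among 10000 random lists of the same number of genes measured on that array. A list stood apart below the 2.5 or above the 97.5 percentile, and the ranks were also adjusted by Benjamini-Hochberg over all pairs of list and array. Intervals of 95% for list medians are from 10000 bootstrap draws over genes. List medians are given relative to the median over all genes of the array, and ratios of single genes as deposited. The intervals describe the genes of 1 array, and genes are not independent replicates.

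To compare the size of differences between groups, the log2 ratio of the mean absolute log ratio on the AT-EAE arrays to that on the control arrays was taken for each gene with values on all 4 arrays. The list median was ranked among random lists in the same way. Channel effects shared by all arrays were tested with limma on the mean ratio of the 4 arrays per spot, with the group means averaged equally, and the AT-EAE minus control difference of the ratio was tested as a check, each with Benjamini-Hochberg adjustment at 0.05. Tests on simulated data recovered 100 of 100 spots shifted by 1 in limma, with 4 unshifted spots called, and 4 of 4 shifted lists, with 6 of 69 unshifted pairs of list and array called. The simulated noise was independent and normal, with 1 spread per array for all spots or genes. Recovery can be lower in the real data, where spots can differ in variance. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used, and R 4.3.3 with limma 3.58.1.

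Groups, tests, gene lists and the rule for naming genes were set before the data were examined. The rule took, among genes with values on all 4 arrays, the 5 highest and 5 lowest ratios of each array. It also took the 10 genes in which the smaller absolute ratio of the AT-EAE arrays most exceeded the larger of the control arrays, and 10 for the reverse. From each list that stood apart on an array it took up to 4 members with the largest absolute ratio there, and likewise up to 4 connexins and pannexins. Alternatives were median centring, genes with values on all 4 arrays, the median over spots, genes with a single spot, subtraction of the mean ratio of the other group, a 1.5-fold threshold, list means, division of each array by its spread, spots with at least 3 values, a replicate block and leaving out each array. Random lists from genes with values on all 4 arrays, a crossed replicate block the removal of spots with an absolute ratio of at least 2, and ribosomal protein and oxidative phosphorylation lists without kinases and assembly factors were added after the data had been seen.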

Results

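The data were 4 arrays of spinal cord, 2 of control mice and 2 of mice with AT-EAE, each giving the log2 ratio between 2 extracts of the same group. Of the 28704 spots, 21139 had a value on control array 1, 18565 on control array 2, 15635 on AT-EAE array 1 and 10788 on AT-EAE array 2. These were 73.6%, 64.7%, 54.5% and 37.6% of the spots. They gave ratios for 8818, 8187, 7398 and 5616 genes, in the same order. Each array was a single measurement of its pair of extracts, without a technical replicate.

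The first question was which genes had a value in which cords. Fewer genes had values in AT-EAE than in control cord, but lists differed in this, and interferon response genes, such as the immunity-related GTPase genes Iigp1 and Irgm1, had slightly more values in AT-EAE. Of 18 genes of this list, 66.7% and 72.2% had a value on control arrays 1 and 2, and 83.3% and 77.8% on AT-EAE arrays 1 and 2. For the 29 microglia and macrophage genes the shares were 89.7% and 79.3% in control, and again 89.7% and 79.3% in AT-EAE. For the 11 complement and acute phase genes they were 72.7% and 63.6% in control, and 90.9% and 63.6% in AT-EAE. Over all 10225 genes, the shares were 86.2% and 80.1% in control, and 72.4% and 54.9% in AT-EAE. Several lists of resident cells also kept most of their values. The shares were 94.1% and 100% in control against 100% and 88.2% in AT-EAE for astrocyte genes, 100% and 94.4% against 94.4% and 88.9% for neuron genes, 100% and 90.9% against 90.9% and 90.9% for oligodendrocyte and myelin genes, and 98.5% and 97.0% against 95.5% and 91.0% for ribosomal protein genes. Other immune lists lost values, with neutrophil genes at 71.4% on both control arrays and 42.9% on both AT-EAE arrays, and B and plasma cell genes at 75.0% on both control arrays and 62.5% and 37.5% on the AT-EAE arrays. Cell cycle genes were at 100% and 92.3% in control and 84.6% and 57.7% in AT-EAE. The skeletal muscle list had values for 82.4% of its genes on both control arrays, and for 58.8% and 52.9% on the AT-EAE arrays.

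**Figure D1:**
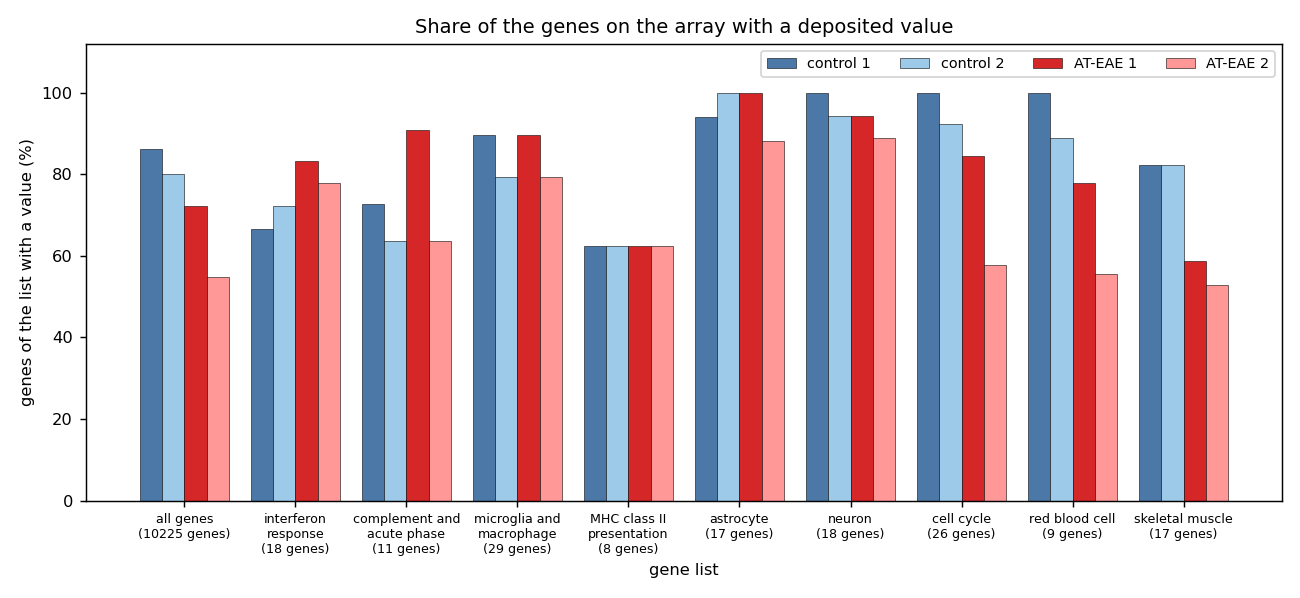
Bars give the percentage of genes with a deposited value on each of the 4 arrays, for all genes and for selected lists. The neutrophil and the B and plasma cell lists, which had fewer values in AT-EAE, are not drawn. Among all genes the share runs from 86.2% on control array 1 to 54.9% on AT-EAE array 2, while in the interferon response list it is 66.7% and 77.8% on the same arrays.

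The second question was how far the extracts of 1 group differed from each other over all genes. Serine hydroxymethyltransferase 2 (Shmt2), a mitochondrial enzyme of one-carbon metabolism, was the 1 gene with at least a 2-fold ratio on both arrays of the control group, and also the 1 such gene on both AT-EAE arrays. Its ratios were -1.002 and -1.04 on control arrays 1 and 2, and -2.81 and -3.11 on AT-EAE arrays 1 and 2. A single Shmt2 spot carried these values, at -2.06, -1.83, -2.81 and -3.11, and the gene's other spot, which had values on the control arrays alone, entered the mean there.

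Genes with at least a 2-fold ratio numbered 12 on control array 1, 32 on control array 2, 27 on AT-EAE array 1 and 60 on AT-EAE array 2. In the same order, 12, 30, 25 and 44 of these had negative ratios, and 0, 2, 2 and 16 had positive ones. Extract numbers are arbitrary, so a lean to negative ratios on every array can come from the channels. The counts therefore do not measure differences between extracts alone. The genes named next are those with the most extreme ratios among genes with values on all 4 arrays, which held 5 of the 12 on control array 1, 11 of the 32 on control array 2 and 13 of the 27 on AT-EAE array 1. On control array 1 the lowest ratios of these were those of the muscle LIM protein gene Csrp3 at -1.29, the neurotrophic factor gene Manf at -1.19, Pitpnb at -1.12 and Prss23 at -1.08, besides Shmt2. The highest were those of the lysosomal genes Fuca1 at 0.79 and Psap at 0.78, and of Rsrp1, Sharpin and Gbp2, each at 0.76. On control array 2 Zmynd11 at -1.79, Prrc2c at -1.52, Hdlbp at -1.34, Cdc40 at -1.21 and Smc1a at -1.19 were lowest. The endosomal GTPase gene Rab5c at 1.26, Eml2 at 1.22, Cckar at 0.94, Cops9 at 0.92 and the ribosomal protein gene Rps10 at 0.89 were highest there.

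On AT-EAE array 1 the lowest ratios besides Shmt2 were those of the mitochondrial ribosome gene Mrpl50 at -2.91, Cbfa2t3 at -2.16, Ocrl at -1.77 and Afp at -1.15. The highest were those of the collagen gene Col5a3 at 1.08, the troponin gene Tnnt2 at 1.01, the small heat shock protein gene Hspb1 at 0.86, Bves at 0.74 and AI413738 at 0.74. On AT-EAE array 2 Gfer at -3.66, the calsequestrin gene Casq2 at -1.55, Noa1 at -1.55 and Cnppd1 at -1.55 were lowest besides Shmt2. Like Shmt2, Cnppd1 had a spot whose ratio limma called as shared by all 4 arrays. The kinesin gene Kif3a at 2.04, Naprt at 1.87, Cbx7 at 1.58, Pigs at 1.41 and Septin3 at 1.31 were highest. Many of these genes were represented by 1 to 3 spots, and a single array gives no error for them.

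The MAD-based standard deviation over genes was 0.18 on control array 1, 0.23 on control array 2, 0.17 on AT-EAE array 1 and 0.33 on AT-EAE array 2. In the same order, the plain standard deviation over genes was 0.21, 0.27, 0.23 and 0.36. Between spots of the same gene it was 0.24, 0.28, 0.24 and 0.36. A gene's ratio is a mean over its spots, which narrows the spread over genes, so it is not directly comparable with the deviation between spots. Over single spots the plain standard deviation was 0.25, 0.31, 0.26 and 0.41, slightly larger than that between spots of a gene. The spread is therefore not a measure of extract differences alone. The mean MAD-based standard deviation over genes was 0.20 ± 0.04 (SD, n = 2 arrays) in control and 0.25 ± 0.11 (SD, n = 2 arrays) in AT-EAE. The difference of 0.05 did not exceed the spread between arrays (2-sided exact permutation p = 1, and 0.333 is the smallest p that 4 arrays allow).

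The third question was whether genes of 1 cell type or pathway shifted together between the 2 extracts of an array, as a difference in inflammation or composition between pools would give. On AT-EAE array 1, the lists for macrophages, MHC class II, complement, cytokines, myelin and connective tissue had medians below that of the array. The microglia and macrophage list had a median of -0.17 relative to the array median (95% interval -0.26 to -0.11), a 1.12-fold difference if the logarithm was to base 2, with 22 of its 26 genes below the median. The lysozyme gene Lyz2 was at -1.01, the macrophage marker Cd68 at -0.76, the lysosomal protease gene Ctsd at -0.70 and the Fc receptor gene Fcgr3 at -0.55. The meninges and fibroblast list was at -0.29 (95% interval -0.33 to -0.14) with 12 of 15 genes below, among them the matrix genes Dcn at -0.91, Col3a1 at -0.72 and Fmod at -0.37, and Serpinf1 at -0.33.

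Further lists below the array median on AT-EAE array 1 were MHC class II presentation at -0.28 (95% interval -0.35 to 0.02), cytokines and chemokines at -0.20 (-0.30 to 0.08), complement and acute phase at -0.19 (-0.29 to 0.01), and oligodendrocyte and myelin at -0.18 (-0.36 to -0.08). The MHC class II genes H2-Aa, H2-Eb1 and H2-Ab1 were at -0.35, -0.30 and -0.22, and the protease gene Ctss, which trims the invariant chain, was at -0.27. The chemokine genes Ccl6, Cxcl12, Ccl9 and Ccl3 were at -0.49, -0.29, -0.24 and -0.22. In the cytokine list 5 of 8 genes lay below the array median and 3 above. In the complement and acute phase list, the C1 inhibitor gene Serping1 was at -0.72, the ceruloplasmin gene Cp at -0.36 and Hpx at -0.28, while Itih3 was at 0.43. The myelin genes Cnp and Mbp were at -0.56 and -0.22, with Tspan2 at -0.38 and Gsn at -0.35. On the same array the oxidative phosphorylation list was slightly above the array median, at 0.06 (95% interval 0.03 to 0.10), with 47 of 71 genes above. Without assembly factors it was at 0.09, with 43 of 63 genes above, and its adjusted p was 0.00465 from random lists. Its members with the largest absolute ratios went both ways, with Ndufb3 at -0.67, Ndufv3 at -0.47, Ndufs5 at -0.42 and Ndufa12 at 0.41.

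On AT-EAE array 2, interferon response genes lay above the array median, at 0.29 (95% interval 0.18 to 0.51), with 13 of 14 genes above. The list no longer stood apart after subtraction of the other group's mean ratio (0.18) or with genes on all 4 arrays (0.23). With single-spot genes it was at 0.52 and stood apart. Iigp1 was at 0.66, the antiviral membrane protein gene Ifitm3 at 0.56, the guanylate-binding protein gene Gbp3 at 0.45 and the cytokine feedback gene Socs3 at 0.44. The 3 measured neutrophil genes lay below the array median, at a list median of -0.49, with the myeloperoxidase gene Mpo at -0.66, S100a8 at -0.57 and the lactoferrin gene Ltf at -0.48. The adult globin genes Hbb-b1 and Hba-a2, picked after their values were seen, were also low on this array, at -0.90 and -0.87. Other red blood cell genes were nearer the array median, with Hbb-bh1 at -0.01, Car1 at -0.13 and Fech at 0.06, and the list was at -0.05. Blood content was not tested for the neutrophil shift.

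On control array 2, the lists for ribosomes and the respiratory chain lay together above the array median. The ribosomal protein list was at 0.29 (95% interval 0.21 to 0.35), with 60 of 65 genes above, and the oxidative phosphorylation list at 0.30 (95% interval 0.22 to 0.35), with 68 of 76 above. Without the S6 kinase genes that share the symbol prefix of ribosomal proteins, 58 of 63 genes lay above at a median of 0.29, and without assembly factors 58 of 65 respiratory chain genes did so at 0.31. Rps10 was at 0.89, Rps3 at 0.86, Rps29 at 0.73 and Rps20 at 0.63. Among respiratory chain genes Ndufb4 was at 0.72, Cox6c at 0.70, Atp5j2 at 0.67 and Ndufs7 at 0.58. The astrocyte list was at 0.14 (95% interval -0.13 to 0.33), but at 0.00 after subtraction of the other group's mean ratio, 0.04 with single-spot genes and 0.12 with genes on all 4 arrays, where it no longer stood apart. Among its genes were Fabp7 at 0.85, the glutamine synthetase gene Glul at 0.61 and Ndrg2 at 0.58, and the glutamate transporter gene Slc1a2 at -0.90. The cell cycle list was at 0.11 (95% interval -0.00111 to 0.21), with Ccnb2 at 0.70, Tyms at 0.47, Bub1 at 0.40 and Mcm5 at -0.38.

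On control array 1, the lists above the array median were red blood cell at 0.21 (95% interval 0.03 to 0.47, and 0.40 with single-spot genes or 0.37 after subtraction of the other group's mean ratio), MHC class II presentation at 0.18 (-0.24 to 0.32), oligodendrocyte and myelin at 0.18 (-0.01 to 0.23), MHC class I and immunoproteasome at 0.15 (0.05 to 0.45), and astrocyte at 0.12 (0.04 to 0.18). MHC class II presentation was at 0.29 after the same subtraction. It no longer stood apart with list means (0.11) or the median over spots (0.18). The subtraction also brings in differences between the extracts of the other group, so a larger value after it is no added support. Over the AT-EAE arrays Hbb-b1 and Hba-a2 had mean ratios of -0.47 and -0.44, which raised the red blood cell value. The globin genes Hbb-b1, Hba-a2 and Hba-x were at 0.54, 0.47 and 0.39, with the carbonic anhydrase gene Car1 at -0.26. H2-Aa was at 0.31 and H2-DMa at 0.18, while H2-Ab1 was at -0.25 and Ctss at 0.18. The MHC class I light chain gene B2m was at 0.56, the immunoproteasome gene Psmb8 at 0.44, Psme1 at 0.24 and Tapbp at -0.33. Mbp was at 0.28, Gsn at 0.27, Trf at 0.23 and Tspan2 at -0.20. Among astrocyte genes Sparcl1 was at 0.56, Ndrg2 at 0.27, Fabp7 at 0.24 and Dbi at 0.24. These 2 lists were not high on control arrays alone. MHC class I and immunoproteasome lay at -0.05 on control array 2, 0.08 on AT-EAE array 1 and 0.27 on AT-EAE array 2. On the last, 7 of 7 genes lay above the median, though the list did not stand apart. The astrocyte list lay at 0.02 on AT-EAE array 1 and 0.16 on AT-EAE array 2, also not apart.

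Of 93 pairs of list and array, 18 stood apart, against 4.65 by chance if genes vary independently. In simulated data with independent genes, 6 of 69 unshifted pairs were called. Genes of 1 list can vary together, which neither the chance count nor the adjusted p allows for. After adjustment over all 93 pairs, 4 remained with the lists as fixed and 5 without kinases and assembly factors. The 4 were the microglia and macrophage list (adjusted p = 0.009 from random lists) and the meninges and fibroblast list (adjusted p = 0.006) on AT-EAE array 1, and the ribosomal protein and oxidative phosphorylation lists (each adjusted p = 0.006) on control array 2. The meninges and fibroblast list no longer stood apart after subtraction of the other group's mean ratio (-0.11) or with single-spot genes (-0.22), and 7 of the 15 calls that could be run with single-spot genes were kept. The microglia and macrophage, ribosomal protein, red blood cell and neutrophil calls, oligodendrocyte and myelin on control array 1 and oxidative phosphorylation on control array 2 were kept under every alternative run for them, though the neutrophil list had too few genes for some, and each of the other calls ended under at least 1. Since the subtraction brings in extract differences of the other group, a call kept or ended by it can owe to those. The shift of the cytokines and chemokines list turned to 0.01 among genes with values on all 4 arrays, that of the oxidative phosphorylation list on AT-EAE array 1 turned to -0.09 after the subtraction, and with genes on all 4 arrays no list stood apart on AT-EAE array 2.

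**Figure D2:**
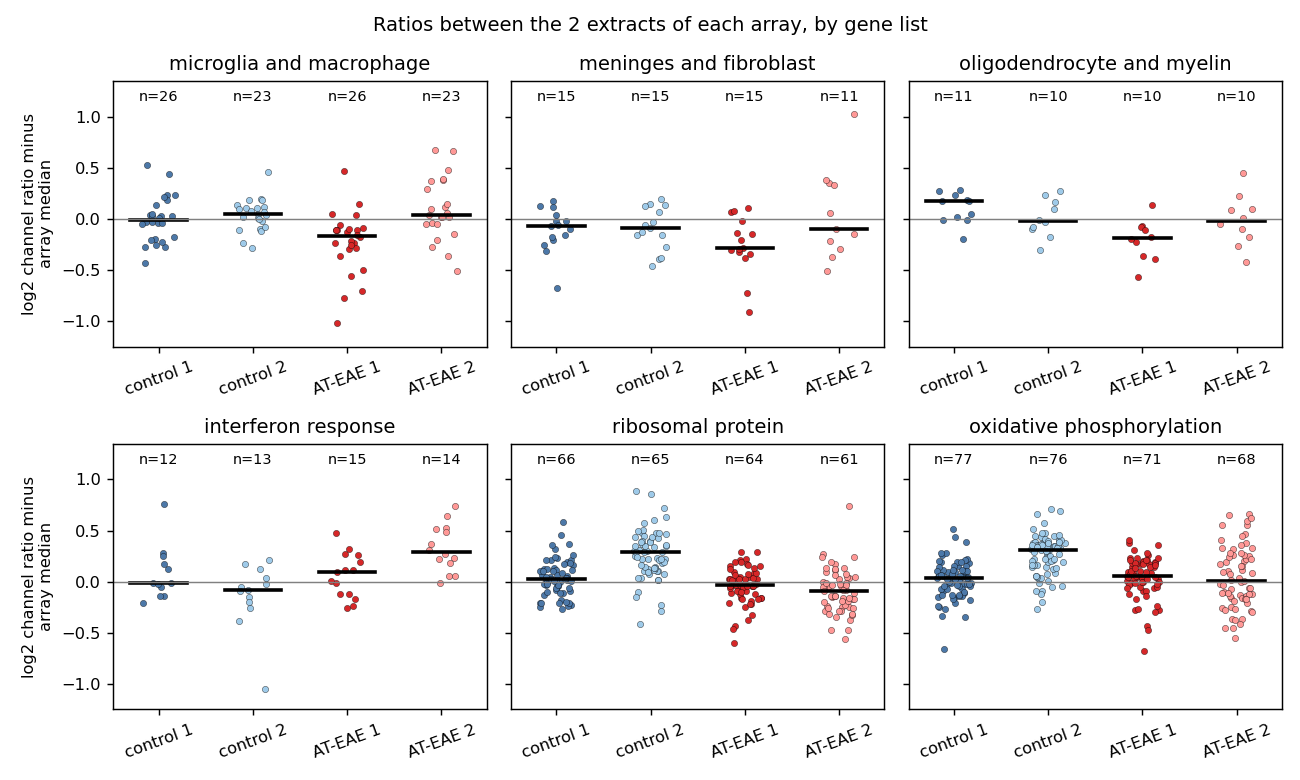
Points give the log2 ratios of the measured genes of selected lists on each of the 4 arrays, relative to the array median, with bars at the list medians. The microglia and macrophage list lies at -0.17 on AT-EAE array 1, the interferon response list at 0.29 on AT-EAE array 2, and the ribosomal protein list at 0.29 on control array 2.

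The fourth question was whether some genes differed more between AT-EAE extracts than between control extracts. The cholesterol synthesis list did so relative to all genes, on 6 measured genes and in a ranking not adjusted over the lists. The median of its genes' mean absolute ratio was 0.30 in AT-EAE and 0.06 in control. The control value was small beside the deviation between spots of a gene there (0.24 and 0.28), so the ratio of the 2 is unstable. The list's median log2 ratio of AT-EAE to control difference was 2.04, against 0.38 over all genes, with 5 of 6 genes above that of all genes (percentile 99.7). The squalene synthase gene Fdft1, Idi1 and Msmo1, chosen after their values were seen, were at 0.18, 0.45 and 0.45 on AT-EAE array 1 and 0.67, 0.20 and 0.33 on AT-EAE array 2. On control arrays 1 and 2, they were at 0.09, 0.02 and -0.04, and at -0.02, 0.10 and 0.13. Members went both ways, with Mvd at -0.03 and -0.47 and Hmgcs1 at 0.12 and -0.44 on the AT-EAE arrays, and Hmgcs1 at -0.35 on control array 2. The ribosomal protein list was at -0.58, the oxidative phosphorylation list at -0.17 and the astrocyte list at -0.54, all below the 2.5 percentile. The other tested lists lay between -0.47 and 0.94, none of them apart. Relative to all genes, the cholesterol synthesis excess was 1.66, and it no longer stood apart without control array 1 (1.31), control array 2 (1.484) or AT-EAE array 2 (1.18). The deficit of the ribosomal protein list was -0.96 and ended without control array 2 (-0.36), that of the oxidative phosphorylation list was -0.55 and ended without control array 2 (-0.15) or AT-EAE array 2 (-0.32), and that of the astrocyte list was -0.91 and ended without each of the 4 arrays in turn (-0.91 to -0.34) and with median centring (-0.24). With single-spot genes, the astrocyte (-0.69) and oxidative phosphorylation (-0.44) deficits also ended, and after subtraction of the other group's mean ratio all 4 list medians equalled that of all genes (0).

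Among 5429 genes with values on all 4 arrays, the smaller AT-EAE ratio exceeded the larger control ratio in absolute size for 1103 genes, and the reverse held for 561, where 905 would be found for each with arrays alike. The arrays were not alike in MAD-based spread, which was 0.33 on AT-EAE array 2 and 0.17 to 0.23 on the others. Unequal spread alone can move these counts. Calcoco1 was at -0.79 and -0.87 on the AT-EAE arrays against -0.04 and -0.15 in control, and Maea at -0.95 and -0.79 against -0.14 and -0.37. Others with this excess were Shmt2, Rbm19, the histone demethylase gene Kdm5c, Tmem256, Col5a3, Kdf1, Col3a1 and Tmem39b. Col3a1 was at -0.72 on AT-EAE array 1 and 0.95 on AT-EAE array 2. The genes with the largest reverse excess were Spock1, Otub1, Gprasp1, P4hb, Mapk8ip3, Prrc2c, Klhl23, Ruvbl2, Trmt61b and the ribosomal protein gene Rps12, which was at 0.35 and 0.48 in control and at -0.01 and -0.05 in AT-EAE. No gene was tested singly here.

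Connexins and pannexins, the gap junction and hemichannel proteins, were looked at as a fixed group. Gja1, which encodes the astrocyte connexin 43, was at -0.55 on AT-EAE array 1 and 0.95 on AT-EAE array 2, against 0.08 and -0.13 on control arrays 1 and 2, from a single spot. Panx1 was at 0.21 and -0.49 in AT-EAE and at -0.14 and 0.18 in control. Gjb5 was at 0.07 on AT-EAE array 1 and at 0.00 and 0.05 in control, and Gja4 had a value on control array 1 alone, of 0.17.

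The last question was which ratios came from the channels and not from the animals, since extract numbers are arbitrary. Spots of Shmt2, Cnppd1, the spliceosome gene Snrnp27 and 1 unnamed spot had ratios below 0 on all 4 arrays, and limma called these 4 of 10133 spots. The mean log2 ratio was -2.45 ± 0.11 (SE, n = 4 arrays, limma adjusted p = 8.39e-06) for Shmt2 and -2.05 ± 0.12 (SE, n = 4 arrays, limma adjusted p = 6.32e-05) for Cnppd1. For Snrnp27 it was -0.80 ± 0.10 (SE, n = 4 arrays, limma adjusted p = 0.0378), and for the unnamed spot -2.08 ± 0.22 (SE, n = 4 arrays, limma adjusted p = 0.00924). At an unadjusted p under 0.05 there were 1276 spots, against 507 by chance. The count of 4 became 41 without control array 1, 48 without control array 2, 749 without AT-EAE array 1 and 140 without AT-EAE array 2. No spot differed in ratio between the AT-EAE and control arrays by limma, and 366 did so at an unadjusted p under 0.05, fewer than the 507 expected by chance. With the array number as a block 21 spots were called, with at least 3 values 3 spots, and 24, 5, 333 and 17 spots without control array 1, control array 2, AT-EAE array 1 and AT-EAE array 2. This last difference carries no meaning for expression in AT-EAE against control.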

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

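The immune comparison of genes lacking control values was set out before its result was seen. So was the test on other spots of genes that had a spot with values in AT-EAE alone. The test against the reverse comparison was chosen afterwards. Outside the ratios themselves, the presence of a value was compared for immune and other genes. The 6 immune lists were MHC class II presentation, MHC class I and immunoproteasome, interferon response, T cell, microglia and macrophage, and neutrophil, and the B and plasma cell list was left among the others. Of 66 genes of these lists with any value, 3 (4.55%) had a value in AT-EAE and none in control, against 0.884% of 8940 other genes. Nearly as many immune genes, 2 (3.03%), had a value in control and none in AT-EAE, against 16.9% of the other genes. Of the 7 neutrophil genes, 71.4% had a value on each control array and 42.9% on each AT-EAE array, and astrocyte, myelin, neuron and ribosomal protein genes, counted among the others, kept most of their values. The 3 immune genes without a control value were the interferon-inducible GTPase genes Iigp1 and Irgm1 and the endotoxin co-receptor gene Cd14, named after their values were seen.

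The odds ratio was 5.34 (95% interval 1.05 to 16.9, 1-sided Fisher exact p = 0.022), which a rise of these transcripts past the spot filter in AT-EAE cord predicts, but among genes with no control value it was 3.26 (0.589 to 12.04, 1-sided Fisher exact p = 0.0865), which does not pass. Immune spots lying near or under the filter on every array stay open, since the odds ratio of 0.114 (95% interval 0.013 to 0.497) for a control value among genes with no AT-EAE value is lowered by spots under the filter on all arrays and by the many other genes without AT-EAE values. Random loss of spots from the control arrays also stays open. Its test began from 177 spots with values in AT-EAE alone, not from the genes above. Of 187 other spots of their genes, 143 (76.5%) had a control value, against 85.1% of spots of other genes. The odds ratio was 0.567 (95% interval 0.4 to 0.817), between the bounds set for and against random loss. Genes without a control value have by definition no other spot with one, so this test cannot address the 3 immune genes. Higher transcript levels in AT-EAE cord may underlie the pattern, as a hypothesis that rests on 3 genes against 2 in reverse, 2 arrays per group and a filter rule not given in the sources used here.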

How the results depend on the processing

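The random lists from genes on all 4 arrays, the crossed block, the removal of spots with large ratios and the trimmed lists were chosen after the data were seen. Of the 18 list shifts, 18 were kept with median centring and 18 with the ribosomal protein and oxidative phosphorylation lists trimmed of kinases and assembly factors, 17 with the median over spots, 14 with list means, 12 of the 17 run with genes on all 4 arrays, 10 after subtraction of the other group's mean and 7 of the 15 run with single-spot genes, the neutrophil list, and for the latter MHC class II on 2 arrays, having too few genes. The cause was not tested where fewer genes or arrays do not show it. After that subtraction the spread became 0.22 on control array 1 and 0.28 on control array 2, AT-EAE array 1 had 17 genes at 2-fold, the oxidative phosphorylation list there reversed to -0.0896 and Shmt2 on control array 1 to 1.96. Genes at 2-fold numbered 5, 11 and 13 on control arrays 1 and 2 and AT-EAE array 1 with genes on all 4 arrays, and 7, 18, 15 and 23 on the 4 arrays with single-spot genes. At 1.5-fold they were 149, 269, 158 and 554. With genes on all 4 arrays, under either choice of random lists, 2 lists stood apart on control array 2 and 0 on AT-EAE array 2, and cytokines and chemokines on AT-EAE array 1 reversed to 0.0148. Single-spot genes left 2 lists on AT-EAE array 1 and 1 on AT-EAE array 2, and list means gave 4 there. Lists with larger differences in AT-EAE numbered 0 with single-spot genes, 2 with arrays divided by their spread, and 0 to 1 when each array was left out (0 without control array 2). Those with smaller differences numbered 1 with single-spot genes, 1 after subtraction and 1 to 2 when each array was left out (1 without AT-EAE array 2). Spots shared by all arrays numbered 8 with at least 3 values, and 41 to 749 when each array was left out (41 without control array 1, 48 without control array 2, 749 without AT-EAE array 1 and 140 without AT-EAE array 2). The difference in ratio was called for 3 spots with at least 3 values, 21 with the replicate block, 0 with the crossed block, and 5 to 333 when each array was left out (24, 5, 333 and 17 in that order), the lone array being assumed to vary like the other group. The ratios pair control array 1 with AT-EAE array 2 and control array 2 with AT-EAE array 1 across genes, which the numbers of the arrays do not. Subtraction gave 2476 of the 5429 genes the same size of difference in both groups by construction, and 14 of 21 lists a median of 0, so that the 4 calls on sizes of differences ended. Alternatives for levels were not run. Signal over background was not analysed here.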

Other observations

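The tests for AT-EAE array 1, whose pool gained the MHC class II list after a first result, the shared channel effect and blood content on control array 2, and the comparison of values present over the 6 immune lists were chosen after the results were seen. A value on both AT-EAE arrays and on neither control array was found for 13 genes, of which 3 are in a fixed list (Iigp1 and Irgm1 for interferon response, Zfp36 for immediate early and stress) and which were named after their values were seen. They were Acod1, which makes itaconate in activated macrophages, the pattern receptor genes Clec7a and Tlr7, the GTPase genes Iigp1 and Irgm1, the inhibitory receptor gene Lilrb4a, the antimicrobial lectin gene Reg3g, and Apobec1, Ctso, Lama4, Srgap2, Steap4 and Zfp36. The reverse, a value on both control arrays and on neither AT-EAE array, held for 935 genes, as fewer spots had values in AT-EAE. Over the 80 genes of the 6 immune lists, 8 had values on more AT-EAE than control arrays and 8 on fewer, against 157 and 3226 of the other genes, an odds ratio of 20.5 (95% interval 6.61 to 63.5, 2-sided Fisher exact p = 2.41e-07). Among the other genes, few of the astrocyte list (0 on more AT-EAE arrays and 1 on fewer) and of the neuron list (1 and 2) differed at all. Genes are not independent replicates, and each group had 2 arrays.

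The remaining lists stood apart on no array. The neuron list lay at 0.01 and 0.06 relative to the array median on control arrays 1 and 2, and at 0.05 and -0.12 on AT-EAE arrays 1 and 2. In the same order, the T cell list lay at -0.07, -0.11, 0.10 and -0.10, and the B and plasma cell list at -0.08, 0.10, 0.06 and 0.05. Adhesion and vessel genes lay at 0.04, -0.02, -0.10 and 0.19, cholesterol synthesis genes at 0.02, -0.06, 0.12 and 0.26, and immediate early and stress genes at 0.01, 0.06, 0.06 and 0.11. Skeletal muscle genes lay at 0.07, 0.06, -0.01 and 0.00, and ependymal and cilia genes at -0.06, 0.18, -0.05 and 0.26. Connexins and pannexins lay at 0.05, 0.04 and 0.06 on the first 3 of these arrays, and Schwann cell and nerve root genes at 0.05 on control array 1 and -0.02 on AT-EAE array 1, with too few genes elsewhere.

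On AT-EAE array 1 the macrophage, MHC class II, complement, cytokine, myelin and fibroblast lists had a pooled median of -0.21 relative to the array median (95% interval -0.25 to -0.14), with 60 of 74 genes below. A channel effect shared by all arrays would repeat the shift, but for the pooled genes the bootstrap intervals of 3 of the 3 other arrays lay clear of the bound set for a repeat. The meninges and fibroblast list by itself lay below the array median on all 4 arrays. It was at -0.07 and -0.09 on control arrays 1 and 2 and at -0.10 on AT-EAE array 2, so a channel effect stays open for that list. Signal-dependent bias stays open: the median of the 57 genes with values on all 4 arrays lay at percentile 0 of random lists of such genes, but the lists were pooled because they lay low here, and signal was not matched. Blood content was argued against by a red blood cell median of -0.0081 (95% interval -0.048 to 0.235). The other immune lists went both ways on this array, none of them apart. Interferon response lay at 0.09 and MHC class I and immunoproteasome at 0.08. The T cell list lay at 0.10, B and plasma cell at 0.06 and neutrophil at -0.09. A difference between the 2 AT-EAE extracts in inflammation or in meninges taken with the cord may underlie the shift of the pooled lists. No biological explanation was tested, since both extracts belong to 1 group.

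On control array 2 the ribosomal protein and oxidative phosphorylation lists had a pooled median of 0.29 (95% interval 0.22 to 0.33), with 128 of 141 genes above. Against a channel effect shared by all arrays, the intervals of 3 of the 3 other arrays lay clear of the bound set for a repeat. Signal-dependent bias stays open, since percentile 100 for the 125 genes with values on all 4 arrays among random lists of such genes follows from pooling lists that lay high, and signal was not matched, and blood content stays open with a red blood cell median of 0.162 (95% interval -0.013 to 0.248). Across genes, which are not independent replicates, control array 2 and AT-EAE array 1 had a Pearson correlation of 0.310, the highest of the 6 pairs of arrays by this coefficient. Control array 1 and AT-EAE array 2 had 0.303, and were higher by Spearman correlation, at 0.330 against 0.326. The ribosomal protein and oxidative phosphorylation genes do not account for the Pearson correlation of 0.310, since it was 0.313 without them. These correlated arrays carried extracts of different groups. An effect common to some arrays but not to all was not tested and stays open. RNA quality or composition could differ between the 2 extracts of control array 2, but no biological explanation was tested.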
